A study of Schizosaccharomyces pombe with 18 samples.

How the data were processed

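Total RNA from 18 cultures of Schizosaccharomyces pombe was measured by RNA sequencing. The labels give 6 genotypes with 3 biological replicates each: wild type and strains deleted for clr1, clr2, clr3, mit1 or chp2 (clr1D, clr2D, clr3D, mit1D and chp2D). Per the labels' protocols, 25 ml cultures were grown in YES medium at 25 °C and 170 rpm, ribosomal RNA was removed with a Ribo-Zero kit for yeast, and libraries were made with a stranded total RNA kit. All strains are labelled h-. The clr2D strain carries his7 as its deletion marker and the other deletions carry drug-resistance markers. Wild type, mit1D and chp2D share the listed arg3 and his3 alleles, whereas the clr deletions list these alleles in another form. Whether this marks another strain background is not known. If it does, background and deletion cannot be told apart in comparisons of a clr deletion with wild type, mit1D or chp2D.

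The deposited table gives 1 FPKM value (fragments per kilobase of transcript per 1e6 fragments) per gene and library, made by the authors, for 7018 genes with their coordinates and transcript lengths. Per the submitters' processing notes, the reads were aligned with GSNAP (version 2013-02-25) to genome build ASM294v2. The counting program and the strand setting of the counting are not given in the sources used here. Reads of a gene and of a gene overlapping it on the other strand therefore cannot be told apart, and values of multicopy families are uncertain. Coordinates are those of the deposited table. The table holds 3 further sample columns that the labels tie to no sample, and they were not used here. Their names continue those of mit1D and chp2D, and what they hold is not known. Gene names came from a reference annotation of assembly ASM294v3, used for names alone: 6844 systematic IDs matched and 4410 of them had a symbol.

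In every library, FPKM multiplied by transcript length came in whole multiples of a smallest unit (100% of the nonzero values within 0.1 read), so the number of reads behind each value could be recovered. Recovered depths ran from 26.17 to 101.85 M reads (1e6). By group they spanned 46.5 to 101.8 M in wild type, 35.4 to 74.6 in clr1D, 42.0 to 82.8 in clr2D, 37.8 to 63.3 in clr3D, 29.2 to 46.5 in mit1D and 26.2 to 32.9 in chp2D. Summed over genes, the reads came to 101.51 to 101.64% of this depth. The depths are a reconstruction from the deposited FPKM. Genes at an FPKM of 0 in all 18 libraries numbered 68.

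Before the data were examined, the groups, the 10 comparisons, the test, the thresholds, the gene lists, the rule for naming genes and the alternatives were fixed, apart from those said below to have been added later. Each library was divided by its median ratio to the geometric mean over the 6484 genes with FPKM of at least 1 in all libraries; these factors lay between 0.971 and 1.067. Genes with FPKM of at least 1 in at least 3 libraries were tested, 6693 in all. Values were analysed as log2 of scaled FPKM plus 1 with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend) in 1 fit of all libraries, with 1 coefficient per genotype. P values are 2-sided and Benjamini-Hochberg adjusted within each comparison; a gene is called changed at an adjusted p under 0.05, with no minimum fold. Levels are mean scaled FPKM ± SD with n = 3 per group. Folds between groups are ratios of these means, and log2 fold changes carry their SE. The added 1 shrinks the log2 fold changes of weakly expressed genes, which then understate the ratio of the means. Other software was Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9, and Biostrings 2.70.1.

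Lists of genes were tested with camera (limma) on the same fit with a preset inter-gene correlation of 0.01, and again with an estimated correlation; p values were adjusted over 21 lists with at least 3 tested members and 10 comparisons, 210 tests. The lists covered the SHREC subunits, heterochromatin and RNAi factors, genes of the P and M mating types, shared mating and sexual differentiation genes, Tf2 retrotransposons, the wtf family, meiotic genes, core stress genes, nitrogen-starvation, iron-acquisition and phosphate-acquisition genes, core histones, cytosolic ribosomal proteins, proteasome subunits, auxotrophic markers, non-coding RNAs and mitochondrially encoded genes. The remaining 3 lists were by position: genes within 100 kb of the ends of chromosomes I and II (subtelomeric), and genes overlapping fixed centromeric and mating-type intervals. A further list, the mating-type cassette genes, had 1 tested member and no test. For each list the number of changed members is also given as adjusted over the list alone. Shared calls of pairs of deletions were set beside the number that independent lists would share and beside 50 simulated draws of unchanged groups against the same wild-type libraries.

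Named genes were chosen by rule. The rule took the 5 SHREC genes, tlh1 and tlh2, and the 8 largest rises and falls of each deletion among changed genes whose 3 libraries all lay on the same side of the 3 wild-type libraries. It took the 5 largest in each direction, by the same condition, between deletions, and up to 2 members in each direction of every list (every member of lists of up to 7). Deleted genes were left out of the ranking. Genes outside the rule are said to have been chosen after their values were seen.

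The titles number the replicates of every group 1 to 3. The library names of wild type and the clr deletions share a prefix for each number and a suffix for each genotype, while mit1D and chp2D have consecutive names of another form. The latter 2 genotypes are called the second library series here. After group means were removed, libraries with the same number correlated across genes at 0.25 to 0.70 within wild type and the clr deletions (18 pairs), at -0.12 to -0.05 between mit1D and chp2D (3 pairs) and at -0.13 to 0.13 across the series (24 pairs). The numbers thus pair samples within the first series; a block term for the replicate number, nested in library series, was run as an alternative. No 2 replicates were copies of one another. No library labelled as wild type belongs to the second series, and whether the 3 unlabelled columns hold one is not known, so that series and genotype cannot be told apart in any comparison of mit1D or chp2D with another group outside the series.

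The fit was tested on simulated counts of mit1D and wild type over 6674 genes, with 50 genes changed at each of 4 folds. It recovered 66% of the changes of 1.2-fold, 92% of 1.5-fold, 100% of 2-fold and 100% of 4-fold, with 3 calls on unchanged genes. The simulated counts had the same dispersion of 0.003 for every gene and group and no pairing by replicate number. Recovery and false calls in the measured libraries may therefore differ. For the same simulated comparison, a list of 30 genes shifted 1.2-fold was called with both correlations, and 0 of 20 unchanged lists were. With 200 genes changed in both mit1D and chp2D, all 171 shared calls fell on changed genes.

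Alternatives were FPKM as deposited, quantile normalization, a pseudocount of 0.1 or 5, no filter on low values, the replicate block, a fit of only the 2 groups compared, a distance of 50 kb for subtelomeric genes, and leaving out each replicate in turn. A test with limma voom on the recovered reads was added after the data had been seen. So were tests of the positions of 2-fold changes without the filter and among genes with a mean scaled FPKM of at least 1 in wild type. All splits of the libraries of each comparison into 3 and 3 were also counted.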

Results

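RNA levels were measured in 18 cultures of fission yeast in 6 groups of 3 biological replicates: wild type and strains deleted for clr1, clr2, clr3, mit1 or chp2, written clr1D, clr2D, clr3D, mit1D and chp2D. The 5 genes encode the subunits of SHREC, a nuclear complex that silences heterochromatin; Clr3 is a histone deacetylase, Mit1 a chromatin remodeler and Chp2 a protein of the HP1 family. Depth, recovered from the deposited FPKM, was 77.47, 46.54 and 101.85 M reads in wild-type replicates 1 to 3. It was 74.62, 35.35 and 52.91 M in clr1D, 55.14, 41.98 and 82.8 in clr2D, and 48.57, 63.33 and 37.85 in clr3D. The second library series was shallower, with 29.25, 30.03 and 46.49 M in mit1D and 32.91, 26.17 and 27.11 in chp2D. Levels are means of scaled FPKM ± SD with n = 3 in every group, log2 fold changes are given ± SE, and positions are on chromosomes I to III of build ASM294v2. Because 1 was added before taking logs, log2 fold changes of weakly expressed genes are smaller than their ratios of means. In each comparison 6693 genes were tested. The strand setting of the counting is not known, so overlapping genes share reads in an unknown way.

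The deleted genes were read first, as a check of each strain's identity. Transcripts of mit1 were almost absent from mit1D, at 0.0158 ± 0.00831 against 13.5 ± 0.266 in wild type (0.117%). The clr3 level in clr3D was 4.93 ± 0.918 against 35.7 ± 0.154 (13.8%), the clr1 level in clr1D 2.41 ± 0.193 against 13.0 ± 0.638 (18.6%), and the chp2 level in chp2D 4.08 ± 0.236 against 13.1 ± 0.583 (31.1%). Reads of clr2 fell least: the level in clr2D was 15.1 ± 0.36 against 19.8 ± 0.504 in wild type (76.2%), with a log2 fold change of -0.37 ± 0.03 (adjusted p = 1.8e-06). The same gene rose to 137% of wild type in clr1D and to 149% in clr3D. The his7 gene, the deletion marker of the clr2D strain per the labels, stood at 337 ± 10.5 in clr2D against 144 ± 2.38 in wild type (234%), and its level in each clr2D library was at least 2.15 times that of any other library.

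**Figure D1:**
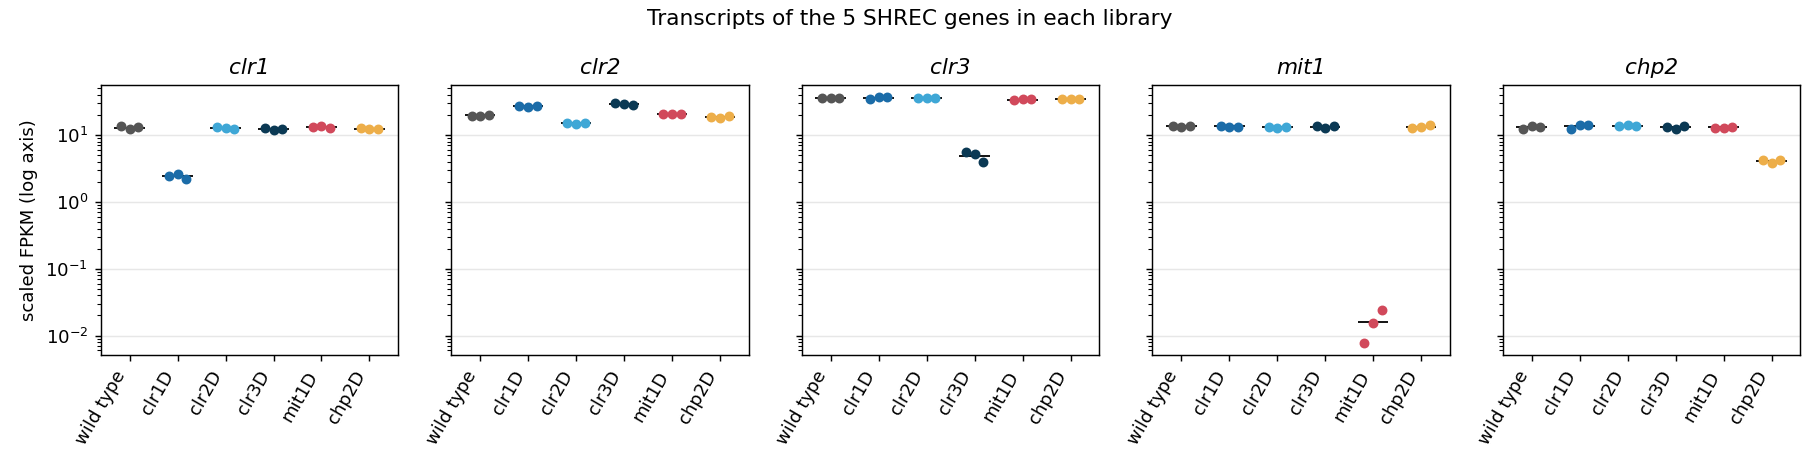
Scaled FPKM (log y axis) of clr1, clr2, clr3, mit1 and chp2, 1 panel each, in the 6 groups (x axis); points are libraries and lines are group means. Each deleted gene is lowest in its own deletion, and clr2 in clr2D stays at 76.2% of wild type.

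Loss of clr1 changed 1178 genes, 623 higher and 555 lower, most by little: the median absolute log2 fold change among them was 0.22, and 32 rises and 20 falls reached 2-fold on the log2 scale. The largest rise on the log2 scale was that of SPBC1289.14 (II 4412072 to 4413599), from 1.73 ± 0.159 to 27.6 ± 3.53 (15.9-fold; log2 fold change 3.38 ± 0.11, adjusted p = 2.9e-12). The neighbouring retrotransposon Tf2-11 rose 2.42-fold, to 11.1 ± 1.03. The non-coding RNAs SPNCRNA.1122 (III 258116 to 258797) and SPNCRNA.1299 (III 2448764 to 2449506) rose 17.3-fold and 6.12-fold, and the RecQ-type helicase gene tlh2 near the right end of chromosome II rose 29.3-fold, from 0.171 ± 0.0209 to 4.99 ± 0.254. The largest fall on the log2 scale lay left of centromere 1. There lys1, which encodes an enzyme of lysine synthesis, fell from 186 ± 7.14 to 31.4 ± 3.16 (5.91-fold; log2 fold change -2.53 ± 0.08, adjusted p = 1.8e-12), and prm1 (I 3736525 to 3743579), whose interval contains lys1, fell 5.54-fold. In clr2D, clr3D, mit1D and chp2D the levels were 90.3, 126, 170 and 163 for prm1 and 137, 192, 260 and 250 for lys1. These 2 genes thus moved together, and the fall of prm1 may not be a separate change. The amino acid permease gene per1 on the same flank fell from 24.5 ± 3.23 to 5.62 ± 0.84 (4.36-fold). Other large falls were those of cbm1 (5.49-fold), the non-coding RNA SPNCRNA.1672 (5.04-fold), the glutamate dehydrogenase gene gdh2 (230 ± 21.6 to 84.3 ± 9.02) and the peroxisomal import receptor gene pex7 (226 ± 7.65 to 86.7 ± 2.07). The fit with a replicate block changed 1977 genes, and the fit of only the 2 groups 543. With FPKM as deposited the higher share rose from 52.9% to 79.4% (960 of 1209), so the split between higher and lower rests on the scaling.

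Among fixed lists, subtelomeric genes were higher as a group in clr1D: 31 of 117 rose and 14 fell (adjusted over the list alone, 35 and 16), and 72 did not pass, with adjusted p = 0.00606 for the list and adjusted p = 0.459 with an estimated correlation. This call was lost with FPKM as deposited (adjusted p = 0.268), with quantile normalization (adjusted p = 0.307) and without the filter (adjusted p = 0.0678). Of 10 tested genes in the centromeric regions 5 rose and 1, per1, fell (adjusted over the list alone, also 5 and 1; adjusted p = 0.00219, or adjusted p = 0.299 with an estimated correlation). The non-coding RNAs SPNCRNA.234 (I 3786105 to 3787136; 0.295 ± 0.0351 to 3.80 ± 0.32) and SPNCRNA.232 (16.1-fold) were among those that rose. Shared mating and sexual differentiation genes were lower, with 5 changed genes among 13, all falls (adjusted over the list alone, 7 falls; adjusted p = 0.0072, or adjusted p = 0.718 with an estimated correlation). The M-factor gene mfm2 also fell, from 98.5 ± 5.46 to 46.1 ± 9.28, although the list of M-cell genes as a whole was not called. Cytosolic ribosomal protein genes were lower by a median log2 fold change of -0.08, with 5 falls among 141 (adjusted over the list alone, 2; adjusted p = 1.33e-06, or adjusted p = 0.835 with an estimated correlation); rps2202 and rpl1002 were among the 5. The fit of only the 2 groups did not call rpl1002 (adjusted p = 0.052). Mitochondrially encoded genes were higher, with 3 rises among 11 (adjusted over the list alone, 4; adjusted p = 0.0072, or adjusted p = 0.677 with an estimated correlation), including SPMIT.02 at 1.3-fold (adjusted p = 0.0605 in the fit of only the 2 groups). Core stress genes had 4 rises among 20, among them srx1 (1.45-fold) and hsp16 (1.3-fold), and the same number adjusted over the list alone (adjusted p = 0.0348, or adjusted p = 0.662 with an estimated correlation, and 0.0696 with FPKM as deposited). The wtf genes, a family of meiotic drivers, had 4 rises among 23, and as many adjusted over the list alone (adjusted p = 0.0315, or adjusted p = 0.766 with an estimated correlation, 0.197 with FPKM as deposited and 0.767 with quantile normalization).

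In clr2D 823 genes changed, 489 higher and 334 lower, of which 31 and 10 reached 2-fold. The genes at the top were largely those of clr1D: SPBC1289.14 rose to 28.9 ± 4.96 (16.7-fold; log2 fold change 3.44 ± 0.11, adjusted p = 3.7e-12), SPNCRNA.1122 rose 16.5-fold and tlh2 34.0-fold, to 5.80 ± 0.107. Near the right end of chromosome I, SPAC186.07c (I 5545615 to 5546613) rose 5.4-fold, with a log2 fold change of 1.83 ± 0.20, as did the overlapping RNA prl61 (4.9-fold). Falls included SPNCRNA.1672 (5.13-fold; -1.84 ± 0.10, adjusted p = 3.7e-09), SPNCRNA.113 (2.92-fold), gdh2 (2.58-fold), cbm1 (2.53-fold), pex7 (to 107 ± 2.58) and per1 (1.87-fold). The fit with a replicate block changed 1534 genes, and the fit of only the 2 groups 323. With FPKM as deposited 559 of 764 changed genes were higher (73.2%, against 59.4%).

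Mating-type region genes (an interval of chromosome II around the silent cassettes) were higher as a group in clr2D and were not called in any other deletion against wild type. Of 16 genes 9 passed and all 9 rose, as many as adjusted over the list alone (adjusted p = 0.000188, or adjusted p = 0.224 with an estimated correlation). They included the proteasome gene rpt6 (109 ± 2.54 to 168 ± 10.9; 1.55-fold), SPBC23G7.14 (179 ± 18.9 to 260 ± 22.0) and the ribosomal protein gene rpp202 (1756 ± 157 to 2448 ± 57.6). These named genes were already expressed in wild type, so their rise does not show the release of silenced genes. Of the 4 cassette genes only 1 was tested and it did not pass. The cause of the rise was not tested. Subtelomeric genes were higher, with 29 rises, 8 falls and 80 not passing (adjusted over the list alone, 34 and 10; adjusted p = 0.00232, or adjusted p = 0.416 with an estimated correlation and 0.14 with quantile normalization). Centromeric genes had 5 rises, among them SPNCRNA.234 (11.4-fold) and SPNCRNA.373 (6.42-fold), and 1 fall (adjusted over the list alone, 5 and 2; adjusted p = 0.006, or adjusted p = 0.374 with an estimated correlation, and 0.0591 with a replicate block). The auxotrophic markers were called through his7 (1 rise of 5, adjusted over the list alone 2; adjusted p = 0.00316, or adjusted p = 0.299 with an estimated correlation). Mating genes were lower, with 2 falls among 13, rgs1 and ste4 (adjusted over the list alone, also 2; adjusted p = 0.00855, or adjusted p = 0.723 with an estimated correlation). The fit of only the 2 groups did not call rgs1 (adjusted p = 0.0663). Mitochondrially encoded genes had 2 rises among 11 (adjusted over the list alone, also 2; adjusted p = 0.00855, or adjusted p = 0.705 with an estimated correlation). Ribosomal protein genes had 1 rise, rpp202, and 2 falls among 141 (adjusted over the list alone, 1 and 1; adjusted p = 0.000411, or adjusted p = 0.905 with an estimated correlation and 0.0982 with quantile normalization). The wtf genes had 3 rises (adjusted over the list alone, also 3; adjusted p = 0.0227, or adjusted p = 0.766 with an estimated correlation), a call lost with FPKM as deposited (adjusted p = 0.0813) and with quantile normalization (adjusted p = 0.639). Core stress genes had 3 rises (adjusted over the list alone, also 3; adjusted p = 0.0455, or adjusted p = 0.662 with an estimated correlation), a call lost with FPKM as deposited (adjusted p = 0.0571) and without the filter (adjusted p = 0.0586).

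Loss of clr3 changed 1941 genes, 994 higher and 947 lower, of which 33 and 14 reached 2-fold. The 2 largest rises on the log2 scale were those of SPBC1289.14, to 37.1 ± 1.76 (21.4-fold; log2 fold change 3.80 ± 0.11, adjusted p = 8e-13), and tlh2, to 10.9 ± 1.59 (63.6-fold). At the left end of chromosome I, SPAC212.06c rose 22.7-fold and SPAC212.12 9.18-fold. The small heat-shock protein gene hsp16 rose from 31.4 ± 1.22 to 66.9 ± 4.55 (2.13-fold). Falls included SPBPB10D8.03 near the left end of chromosome II (3.73 ± 0.707 to 0.645 ± 0.36; -1.53 ± 0.18, adjusted p = 2.3e-05), SPNCRNA.1672 (4.07-fold), cbm1 (2.6-fold), and the glutathione transferase genes gst1 (1.75-fold) and gst2 (1.48-fold). SPNCRNA.1331, which overlaps clr3, fell 6.13-fold with the deleted gene. The fit of only the 2 groups changed 1082 genes.

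Of the 117 subtelomeric genes 44 rose in clr3D, 11 fell and 62 did not pass (adjusted over the list alone, 46 and 12; adjusted p = 9.29e-07, or adjusted p = 0.171 with an estimated correlation). Of centromeric genes 6 passed and all 6 rose (adjusted over the list alone, the same; adjusted p = 0.000144, or adjusted p = 0.175 with an estimated correlation), with SPNCRNA.234 at 11.6-fold and SPNCRNA.373 at 8.73-fold. Proteasome genes were higher by a small amount: 18 of 33 passed and all 18 rose (adjusted over the list alone, 21), with a median log2 fold change of 0.11. Their test gave adjusted p = 1.91e-06, or adjusted p = 0.662 with an estimated correlation, and pre9 rose from 123 ± 1.19 to 149 ± 4.28. The same list was called as higher in clr1D and clr2D only with FPKM as deposited (adjusted p = 0.0145 and adjusted p = 0.0258) or quantile normalization (adjusted p = 0.00194 and adjusted p = 0.00301). Under the same alternatives it was called as lower in mit1D (adjusted p = 0.00563 and adjusted p = 0.0158) and in chp2D (adjusted p = 0.0245 and adjusted p = 0.049). The wtf genes moved opposite to clr1D and clr2D, with 8 changed genes among 23, all falls (adjusted over the list alone, 9 falls; adjusted p = 0.00292, or adjusted p = 0.723 with an estimated correlation), including wtf12 (1.68-fold) and wtf16 (1.99-fold). Mitochondrially encoded genes had 5 rises among 11 (adjusted over the list alone, also 5; adjusted p = 0.00494, or adjusted p = 0.662 with an estimated correlation). Ribosomal protein genes had 4 falls among 141 (adjusted over the list alone, 1; adjusted p = 0.00159, or adjusted p = 0.905 with an estimated correlation). Of nitrogen-starvation genes 6 of 10 rose and 1 fell (adjusted over the list alone, 6 and 2), but the list was not called (adjusted p = 0.191).

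In mit1D 1820 genes changed, 984 higher and 836 lower, and 31 and 22 of them reached 2-fold. The largest rises on the log2 scale were at the left end of chromosome I, where SPAC212.12 (I 15855 to 16226) rose from 0.907 ± 0.275 to 43.1 ± 6.35 (47.6-fold; log2 fold change 4.53 ± 0.15, adjusted p = 4.8e-12) and SPAC212.08c (I 11784 to 12994) from 0.134 ± 0.0104 to 16.6 ± 1.97 (124-fold). The non-coding RNA SPNCRNA.934, left of centromere 1, rose from 23.2 ± 3.56 to 104 ± 5.41 (4.47-fold), and the alanine racemase gene alr2 from 15.9 ± 4.57 to 60.6 ± 5.02 (3.8-fold). The gene nbr1 rose from 22.0 ± 0.679 to 105 ± 7.74, but it overlaps the end of the deleted gene. Falls included omt3 (6.56-fold; -2.33 ± 0.22, adjusted p = 2.7e-06), the meiotic regulator gene mei2 (12.6 ± 3.23 to 2.48 ± 0.471) and the glyceraldehyde phosphate dehydrogenase gene gpd3 (316 ± 52.0 to 86.6 ± 2.61). At III 1646645 to 1649005, SPCC663.07c stood at 0.222 ± 0.104 against 18.9 ± 8.20, SPNCRNA.1213 at 0.328 ± 0.0661 against 21.4 ± 8.01 and SPCC663.08c at 0.0168 ± 0.0157 against 27.5 ± 10.2. Deletion and library series cannot be told apart in this comparison. With FPKM as deposited 728 of 1843 changed genes were higher (39.5%, against 54.1%).

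Iron-acquisition genes were lower in mit1D: 1 of 10 rose and 6 fell (adjusted over the list alone, 1 and 7; adjusted p = 0.00709, or adjusted p = 0.723 with an estimated correlation). The ferroxidase gene fio1 fell from 121 ± 62.5 to 42.3 ± 12.7 and the heme uptake gene shu1 from 3.21 ± 1.41 to 0.622 ± 0.099; the wild-type libraries were widely spread for both. Another member, str3, was called at adjusted p = 0.0211 but not without wild-type replicate 3 (adjusted p = 0.115), without mit1D replicate 2 (adjusted p = 0.108), in the fit of only the 2 groups (adjusted p = 0.0593) or by voom (adjusted p = 0.0525). Mitochondrially encoded genes were higher, with 8 rises among 11 (adjusted over the list alone, 9; adjusted p = 3.41e-05, or adjusted p = 0.422 with an estimated correlation); SPMIT.03 rose 1.8-fold and SPMIT.02 1.69-fold. Ribosomal protein genes were lower, with 1 rise and 37 falls among 141, the same counts adjusted over the list alone (adjusted p = 1.26e-05, or adjusted p = 0.87 with an estimated correlation), and rps3001 and rpl4102 fell 1.4-fold. Of centromeric genes 6 passed and all 6 rose (adjusted over the list alone, 7; adjusted p = 0.000131, or adjusted p = 0.175 with an estimated correlation), with SPNCRNA.234 at 7.37-fold. Subtelomeric genes had 31 rises, 19 falls and 67 not passing (adjusted over the list alone, 36 and 21). That list was not called (adjusted p = 0.0999), but it was with FPKM as deposited (adjusted p = 0.00718) and with quantile normalization (adjusted p = 0.0246).

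In chp2D 1513 genes changed, 800 higher and 713 lower, with 19 and 15 at 2-fold or more. The same genes led as in mit1D: SPAC212.12 rose to 44.6 ± 5.80 (49.1-fold; log2 fold change 4.58 ± 0.15, adjusted p = 1e-11), SPAC212.08c to 16.7 ± 1.73 (124-fold), alr2 to 63.4 ± 2.77 (3.98-fold) and SPNCRNA.934 3.85-fold. Among falls were omt3 (6.72-fold; -2.36 ± 0.22, adjusted p = 3.8e-06), mei2 (4.7-fold), gpd3 (3.27-fold), mug14 (2.67-fold) and the glucose transporter gene ght5, from 92.0 ± 36.4 to 36.4 ± 1.55. Deletion and library series cannot be told apart here either. With FPKM as deposited 535 of 1624 changed genes were higher (32.9%, against 52.9%).

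Meiotic genes were lower in chp2D, with 1 rise and 10 falls among 21 (adjusted over the list alone, 2 and 10; adjusted p = 0.00384, or adjusted p = 0.314 with an estimated correlation), including mug10 (1.7-fold) and spo5 (1.73-fold). In mit1D the same list had 2 rises and 8 falls and was not called (adjusted p = 0.109). Iron-acquisition genes had 5 changed genes among 10, all falls (adjusted over the list alone, 7 falls; adjusted p = 0.00364, or adjusted p = 0.718 with an estimated correlation), with shu1 8.05-fold lower. Shared mating genes had 1 rise and 4 falls among 13, the same adjusted over the list alone (adjusted p = 0.03, or adjusted p = 0.745 with an estimated correlation), a call lost with FPKM as deposited (adjusted p = 0.0846) and with quantile normalization (adjusted p = 0.0663). Mitochondrially encoded genes had 8 rises among 11 (adjusted over the list alone, 9; adjusted p = 7.84e-05, or adjusted p = 0.459 with an estimated correlation), with SPMIT.03 at 1.64-fold. Of centromeric genes 5 passed and all 5 rose, as many as adjusted over the list alone (adjusted p = 0.000188, or adjusted p = 0.175 with an estimated correlation). Subtelomeric genes had 24 rises and 24 falls (adjusted over the list alone, 26 and 26) and were not called (adjusted p = 0.346), except with FPKM as deposited (adjusted p = 0.0196). Ribosomal protein genes had 5 rises and 17 falls (adjusted over the list alone, 2 and 14) and were not called (adjusted p = 0.223), except with FPKM as deposited (adjusted p = 0.0116).

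Heterochromatin and RNAi factors, 18 genes tested, were not called as a list against wild type: 2 rose and 2 fell in clr1D, 1 and 0 in clr2D, 1 and 3 in clr3D, 4 and 2 in mit1D, and 1 and 1 in chp2D. Among them epe1 fell 1.16-fold in clr3D and 1.15-fold in clr1D. The clr1D call was lost with FPKM as deposited (adjusted p = 0.0702) and in the fit of only the 2 groups (adjusted p = 0.0602). It also fell 1.11-fold in mit1D, a call lost with any of 4 libraries left out (adjusted p = 0.0539 to 0.0812). Of 13 Tf2 retrotransposons only 3 passed the FPKM filter and were tested, and their list was not called. Core histone genes, 11 tested, had at most 1 rise and 1 fall in any deletion, with hht2 1.2-fold lower in mit1D. The lists of SHREC, P-cell and M-cell genes were not called either, nor were the 3 phosphate-acquisition genes, except in clr1D as lower with FPKM as deposited (adjusted p = 0.0464) or a replicate block (adjusted p = 0.0457). Non-coding RNAs, 1448 tested, had 203 rises and 114 falls in clr1D, 158 and 75 in clr2D, 208 and 196 in clr3D, 223 and 157 in mit1D, and 182 and 160 in chp2D, and were not called as a list. Of the mating-type cassette genes 1 of 4 was tested, mat1-Mi, which passed in no comparison, with or without adjustment, by limma or by voom. In the whole set of 210 list tests there were 50 calls, of which 2 held with an estimated correlation: mating-type region genes and auxotrophic markers in clr1D against clr2D. The call of the markers came through his7, the deletion marker of clr2D, and so follows from how that strain was made. The median, the mean and the test differed in sign in 26 tests and in 0 of the 50 calls.

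Genes that rose 2-fold or more were over-represented near the ends of chromosomes I and II in every deletion. Within 100 kb of an end lay 17 of 33 such genes in clr3D, 13 of 31 in mit1D, 11 of 31 in clr2D, 9 of 32 in clr1D and 9 of 19 in chp2D, against 117 of the 6693 tested (1.75%). Adjusted p values of Fisher's exact test, 2-sided, ran from 3.72e-21 in clr3D to 4.48e-09 in clr1D, with neighbouring genes counted as if independent. The filter admits genes silent in wild type, such as tlh2, only because they rise in deletions, so 2 tests were added after the data were seen. Without the filter the counts of rises were the same against 175 of 6950 genes (2.52%), with adjusted p from 2.47e-18 in clr3D to 1.13e-07 in clr1D. Among genes at 1 or more in wild type (102 of 6617 subtelomeric, 1.54%), fewer rises remained: 9 of 19 in clr3D, 5 of 21 in mit1D, 4 of 17 in clr2D, 3 of 18 in clr1D and 2 of 10 in chp2D (adjusted p = 2.79e-11 in clr3D to adjusted p = 0.0122 in chp2D). Of 2-fold falls, those of clr1D and clr2D all lay elsewhere, against 4 of 14 in clr3D (adjusted p = 0.000129), 3 of 22 in mit1D (adjusted p = 0.00786) and 3 of 15 in chp2D (adjusted p = 0.0029). The counts by arm were not tested for a difference between deletions. At the left end of chromosome II, 0 of 24 genes rose by limma in clr1D, clr2D or clr3D (at unadjusted p under 0.05, 4, 2 and 0; by voom, 0 in each) while 7, 3 and 8 fell; 9 rose and 4 fell in mit1D, and 4 rose and 5 fell in chp2D. At the right end of chromosome II, 9 of 25 genes rose in clr1D and in clr2D, 16 in clr3D, 4 in mit1D and 5 in chp2D, and 1 fell in each of clr1D, clr2D and chp2D. At the right end of chromosome I, of 33 genes 13 rose and 2 fell in clr1D, 12 and 1 in clr2D, 16 and 2 in clr3D, 8 and 3 in mit1D, and 8 and 4 in chp2D. At the left end of chromosome I, of 35 genes 9 rose and 4 fell in clr1D, 8 and 3 in clr2D, 12 and 1 in clr3D, 10 and 12 in mit1D, and 7 and 14 in chp2D. The gene tlh2 rose in all 5 deletions, to 2.19 ± 0.187 in mit1D and 2.77 ± 0.101 in chp2D, and was higher in clr3D than in mit1D by 1.89 on the log2 scale. Its paralogue tlh1, which was below the level for testing, was listed at 0.0109 in wild type and between 0.33 and 0.723 in the deletions.

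**Figure D2:**
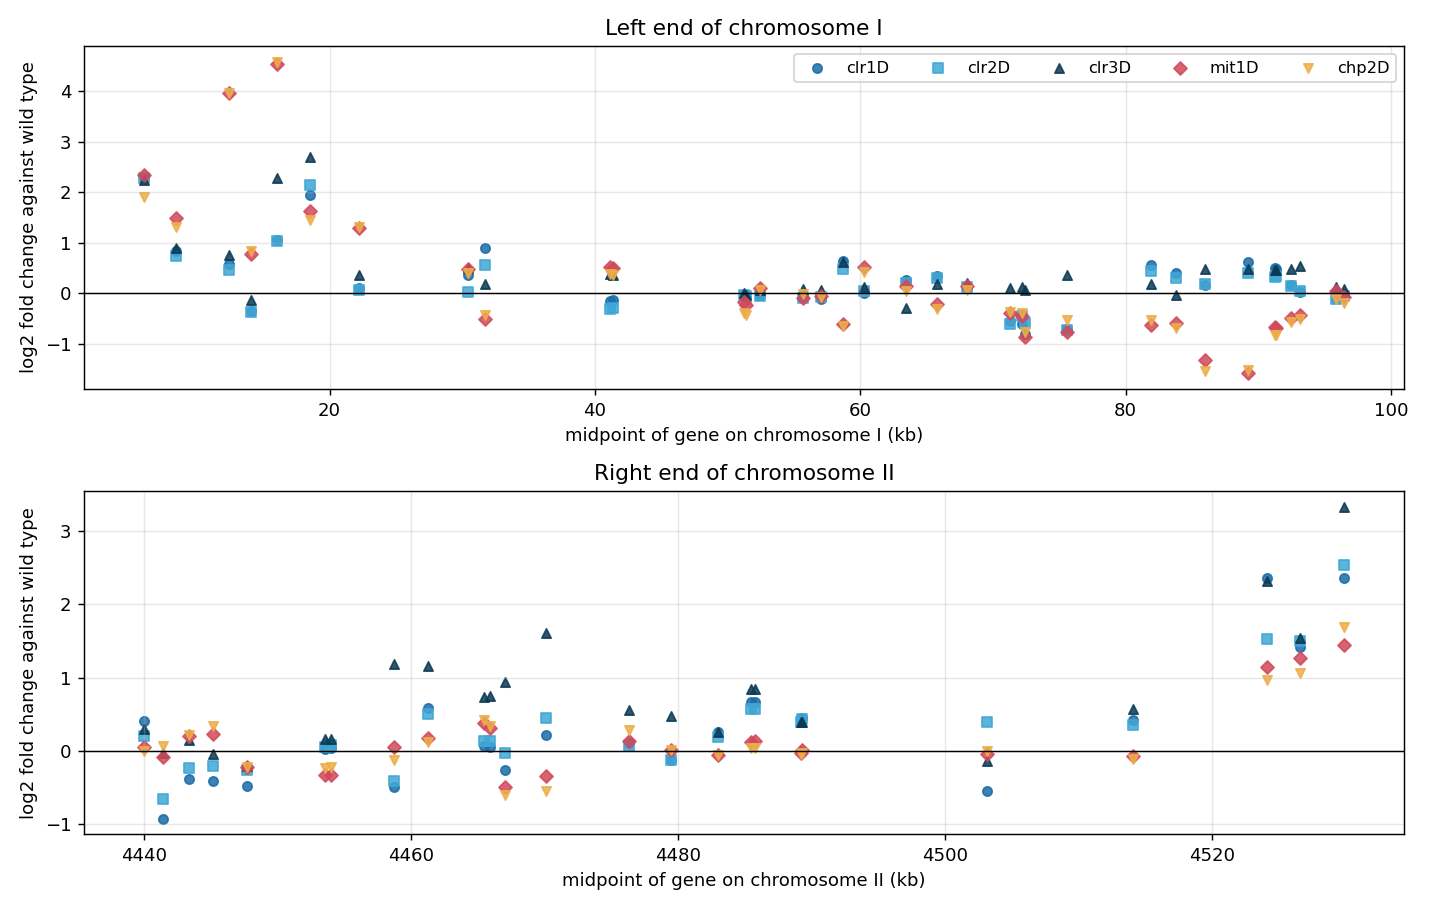
Log2 fold change against wild type (y axis) by gene midpoint in kb (x axis) for tested genes within 100 kb of the left end of chromosome I and the right end of chromosome II; points are genes, with a color and shape for each of the 5 deletions. At the right end of chromosome II, 9 of 25 genes rose in clr1D and in clr2D, 16 in clr3D, 4 in mit1D and 5 in chp2D.

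Calls were shared most between clr1D and clr2D and between mit1D and chp2D. Of the genes higher in clr2D, 428 were also higher in clr1D (45.5 under independence), and 305 were lower in both (27.7 under independence), with 4 in opposite directions; cbm1, gdh2 and pex7 were among those lower. Between mit1D and chp2D 687 higher and 556 lower calls were shared (117.6 and 89.1 under independence), and no gene was called in opposite directions. Among those lower were omt3, mei2 and gpd3. Both deletions are of the second library series and wild type is of the first. Sharing due to the series therefore cannot be told apart from sharing due to the deletions, for these calls or for the correlation and covariance below. Between clr1D and clr3D 287 and 146 were shared (92.5 and 78.5 under independence), and between clr2D and clr3D 249 and 115 (72.6 and 47.3). Between clr3D and mit1D 232 and 152 were shared (146.1 and 118.3 under independence) while 210 moved in opposite directions. Simulated unchanged groups that shared the wild-type libraries had 0.02 shared calls at most on average, over 50 draws. These draws held no changed gene and no difference between library series, so almost no calls could arise in them. They cannot show how many shared calls the common wild-type libraries add to lists of the length seen here. Across genes, which are not independent replicates, log2 fold changes correlated at 0.91 between clr1D and clr2D, 0.84 between mit1D and chp2D, 0.56 between clr1D and clr3D, 0.59 between clr2D and clr3D, and 0.19 between clr3D and mit1D. The shared wild-type libraries alone gave about 0.5 in simulation, so these values were read beside the covariance. It was 0.042 for clr1D and clr2D, 0.0472 for mit1D and chp2D and 0.0109 for clr3D and mit1D. For clr3D it was 0.0281 with clr1D and 0.0271 with clr2D. Simulated covariances were 0.00323 to 0.00333. In all 5 deletions 56 genes were higher and 16 lower. Those that rose 2-fold or more in all 5 numbered 7, the subtelomeric SPAC212.06c, SPAC212.10, SPAC212.12, SPBCPT2R1.10 and tlh2 and the centromeric SPNCRNA.234 and SPNCRNA.373; SPBCPT2R1.10 falls outside the naming rule and was chosen after its values were seen. In the 3 clr deletions 231 genes were higher and 107 lower. Those with 2-fold falls were cbm1, SPNCRNA.113, SPNCRNA.1672 and SPNCRNA.1674. The clr deletions also list arg3 and his3 alleles in another form than wild type. Sharing due to such a difference, if real, cannot be told apart from sharing due to the deletions.

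**Figure D3:**
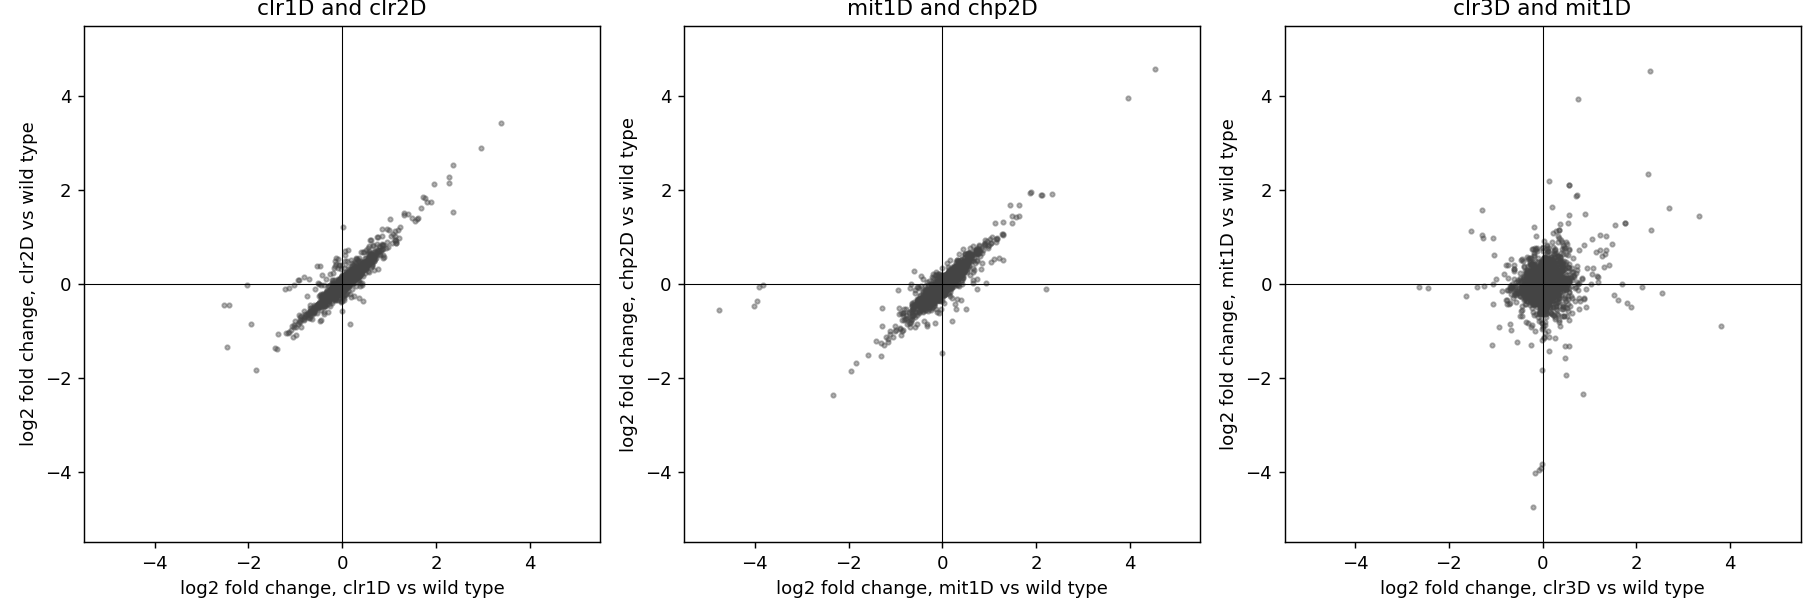
Log2 fold changes against wild type of pairs of deletions (x and y axes), 1 point per tested gene. The points follow the diagonal for clr1D with clr2D (r = 0.91) and for mit1D with chp2D (r = 0.84) and scatter for clr3D with mit1D (r = 0.19). For mit1D with chp2D, library series and deletion cannot be told apart.

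The direct comparison of clr1D with clr2D asked how alike the 2 deletions were, with clr2 still at 76.2% of wild type in clr2D. Only 32 genes differed, 7 higher and 25 lower in clr1D, with 11 of the latter by 2-fold. The largest difference on the log2 scale was in lys1, at 31.4 ± 3.16 in clr1D and 137 ± 13.4 in clr2D (log2 fold change -2.09 ± 0.08, adjusted p = 3e-11), with prm1 4.1-fold lower and per1 2.33-fold lower in clr1D. The copper amine oxidase gene cao1 was at 32.0 ± 1.51 against 70.0 ± 3.17, and the overlapping SPNCRNA.860 was 2.17-fold lower. The next gene, cbm1, was 2.17-fold lower (adjusted p = 0.031), but not without clr1D replicate 1 (adjusted p = 0.265), clr1D replicate 3 (adjusted p = 0.209) or clr2D replicate 2 (adjusted p = 0.225). Nor did it pass in the fit of only the 2 groups (adjusted p = 0.572). Genes higher in clr1D included mhf1 (41.2 ± 0.599 against 32.9 ± 0.798) and SPNCRNA.1569 next to clr1, and chk1 (1.26-fold; adjusted p = 0.0616 in the fit of only the 2 groups). Mating-type region genes were lower in clr1D, with 8 changed genes among 16, all falls (adjusted over the list alone, 10; adjusted p = 7.49e-34, or adjusted p = 0.000197 with an estimated correlation), rpt6 1.49-fold. The auxotrophic markers were lower through his7 (1 of 5, adjusted over the list alone 2; adjusted p = 1e-09, or adjusted p = 0.0173 with an estimated correlation). Ribosomal protein genes were lower by a median of -0.03, with only rpp202 passing (adjusted over the list alone, also 1; adjusted p = 0.000235, or adjusted p = 0.905 with an estimated correlation and 0.158 with quantile normalization).

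**Figure D4:**
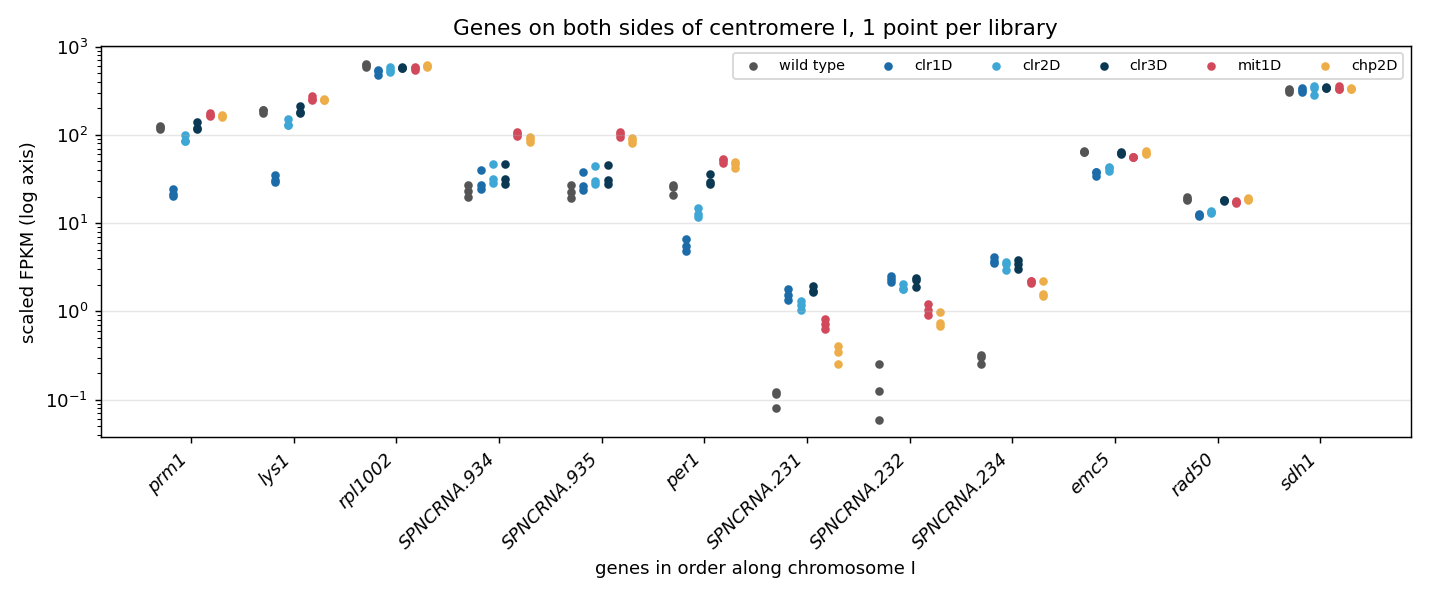
Scaled FPKM (log y axis) of genes on both sides of centromere 1, in their order along chromosome I (x axis); each point is a library, colored by group. On the left flank lys1 and prm1 are lowest in clr1D, with means of 31.4 and 22.1, and SPNCRNA.934 is highest in mit1D, with a mean of 104.

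Between clr1D and clr3D 2353 genes differed, 1142 higher and 1211 lower in clr1D, of which 7 and 19 by 2-fold. Besides the deleted genes, SPBPB10D8.03 was 5.52-fold higher in clr1D (log2 fold change 1.48 ± 0.18, adjusted p = 3.4e-05), frp2 2.36-fold and rem1 2.76-fold higher. Lower in clr1D were lys1 (6.09-fold; -2.57 ± 0.08, adjusted p = 1.2e-12), per1 (5.53-fold), omt3 (3.77-fold) and the subtelomeric gene nrg1 (4.12-fold). The gene hsp16 was 1.64-fold lower and isp7 1.68-fold lower. The wtf genes were higher in clr1D, with 14 of 23 passing and all 14 higher, as adjusted over the list alone (adjusted p = 2.45e-05, or adjusted p = 0.591 with an estimated correlation), wtf16 2.65-fold. Subtelomeric genes were lower, with 10 higher, 35 lower and 72 not passing (adjusted over the list alone, 10 and 36; adjusted p = 0.00818, or adjusted p = 0.505 with an estimated correlation, and 0.0687 without the filter). Proteasome genes were lower, with 14 of 33 passing and all 14 lower (adjusted over the list alone, 15; adjusted p = 0.00269, or adjusted p = 0.766 with an estimated correlation, and 0.62 with quantile normalization). The fit of only the 2 groups gave 1493 genes, and with FPKM as deposited 1571 of 2197 differing genes were higher in clr1D (71.5%, against 48.5%).

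Between clr2D and clr3D 2121 genes differed, 1050 higher and 1071 lower in clr2D, of which 6 and 8 by 2-fold. The genes SPBPB10D8.03 (6.08-fold; log2 fold change 1.57 ± 0.18, adjusted p = 2.3e-05), rem1 (2.67-fold) and SPBC23G7.10c in the mating-type region (20.1 ± 2.30 against 9.43 ± 1.12) were higher in clr2D. Lower were omt3 (3.38-fold; -1.62 ± 0.22, adjusted p = 7.9e-05), nrg1 (3.81-fold), the uracil-regulated gene urg1 (29.4 ± 4.32 against 77.1 ± 17.7), SPAC212.12 (2.88-fold) and per1 (2.37-fold). Mating-type region genes had 10 rises and 1 fall, as adjusted over the list alone (adjusted p = 6.7e-05, or adjusted p = 0.175 with an estimated correlation). Of the wtf genes 14 passed and all 14 were higher, as adjusted over the list alone (adjusted p = 1.19e-05, or adjusted p = 0.564 with an estimated correlation). Subtelomeric genes had 10 rises and 35 falls (adjusted over the list alone, 10 and 37; adjusted p = 0.00606, or adjusted p = 0.459 with an estimated correlation, and 0.0865 without the filter). Proteasome genes had 1 rise, rpt6, and 14 falls (adjusted over the list alone, 1 and 15; adjusted p = 0.00292, or adjusted p = 0.766 with an estimated correlation, and 0.451 with quantile normalization). Of the auxotrophic markers his7 and ade6 were higher (adjusted over the list alone, 3; adjusted p = 0.0206, or adjusted p = 0.459 with an estimated correlation). The fit of only the 2 groups gave 1253 genes, and with FPKM as deposited 1202 of 1898 were higher (63.3%, against 49.5%).

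Between mit1D and chp2D, which belong to the same library series, 11 genes differed, 6 higher and 5 lower in mit1D. Of these, 5 lie at the deleted genes: mit1 and SPNCRNA.1401 within it were lower and chp2, nbr1 (105 ± 7.74 against 20.3 ± 1.03; log2 fold change 2.32 ± 0.05, adjusted p = 3.7e-14) and usp103 (40.6 ± 0.777 against 22.0 ± 0.876) higher in mit1D, the last 2 flanking mit1. The 3 genes SPCC663.07c, SPNCRNA.1213 and SPCC663.08c were at 13.8 ± 0.839, 14.5 ± 0.34 and 17.7 ± 0.655 in chp2D and near 0 in mit1D. The other differences were of at most 1.38-fold, in the overlapping SPNCRNA.1298 and SPCC569.02c and in ysa1, which lies next to nbr1 near the deleted mit1. The first 2 passed with chp2D replicate 3 left out but not with any other library of the pair left out (adjusted p = 0.0942 to 0.217, and 0.079 to 0.217). They did not pass with quantile normalization (adjusted p = 0.193 and adjusted p = 0.161), a pseudocount of 5 (adjusted p = 0.0546 and adjusted p = 0.0551) or the fit of only the 2 groups (adjusted p = 0.109 and adjusted p = 0.124). For its part ysa1 did not pass without mit1D replicate 3 (adjusted p = 0.0517) or chp2D replicate 1 (adjusted p = 0.0736). With voom on recovered reads 7 genes differed. The 4 that did not pass were SPNCRNA.1298 (adjusted p = 0.542), SPCC569.02c (adjusted p = 0.436), SPNCRNA.1213 (adjusted p = 0.0563) and SPCC663.08c (adjusted p = 0.199). The last 2 had 66 and 2 recovered reads in mit1D in total, against 16 for SPCC663.07c, which passed. The cause was not tested. The lists called here had 0 genes passing the adjusted test of single genes: ribosomal protein genes were lower in mit1D by a median of -0.06 (adjusted p = 3.5e-15, or adjusted p = 0.727 with an estimated correlation). Meiotic genes were higher by a median of 0.06 (adjusted p = 0.00267, or adjusted p = 0.299 with an estimated correlation). Subtelomeric genes were higher by a median of 0.06 (adjusted p = 0.0226, or adjusted p = 0.63 with an estimated correlation, and 0.0547 without the filter), and centromeric genes by 0.1 (adjusted p = 0.0484, or adjusted p = 0.601 with an estimated correlation). The centromeric call was lost without the filter (adjusted p = 0.276), with a pseudocount of 0.1 (adjusted p = 0.0666) or 5 (adjusted p = 0.0664) and with FPKM as deposited (adjusted p = 0.0651). Adjusted over the list alone 1 centromeric gene and 0 genes of the other 3 lists passed. By limma at unadjusted p under 0.05, the genes passing were 1 ribosomal, 3 meiotic, 5 subtelomeric and 2 centromeric, and by voom 0 in each list.

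Between clr3D and mit1D, the deacetylase and the remodeler, 3044 genes differed, 1469 higher and 1575 lower in clr3D, of which 54 and 28 by 2-fold. The largest difference on the log2 scale was in SPBC1289.14, at 37.1 ± 1.76 in clr3D and 0.465 ± 0.094 in mit1D (79.7-fold; log2 fold change 4.70 ± 0.11, adjusted p = 3.1e-14). Higher in clr3D were also mei2 (7.47-fold), SPAC186.07c (10.1-fold), shu1 (7.76-fold) and the metallothionein gene zym1 (32.6 ± 1.44 against 12.4 ± 1.30). Lower in clr3D were SPAC212.08c (0.922 ± 0.0688 against 16.6 ± 1.97; -3.19 ± 0.09, adjusted p = 3.6e-13), SPBC460.05 (7.89-fold; -2.87 ± 0.25), SPBPB10D8.03 (14.5-fold; -2.67 ± 0.18) and SPNCRNA.1307 (5.26-fold; -2.34 ± 0.31). Of subtelomeric genes 49 were higher, 23 lower and 45 did not pass (adjusted over the list alone, 51 and 23; adjusted p = 0.0147, or adjusted p = 0.591 with an estimated correlation), a call lost with FPKM as deposited (adjusted p = 0.0619) and without the filter (adjusted p = 0.109). Proteasome genes were higher, with 23 of 33 passing and all 23 higher, as adjusted over the list alone (adjusted p = 4.21e-07, or adjusted p = 0.662 with an estimated correlation), pre10 1.28-fold. Iron-acquisition genes were higher, 8 of 10 with 1 lower (adjusted over the list alone, 9 and 1; adjusted p = 0.0144, or adjusted p = 0.727 with an estimated correlation). The wtf genes were lower, with 13 of 23 passing and all 13 lower, as adjusted over the list alone (adjusted p = 0.00847, or adjusted p = 0.753 with an estimated correlation), wtf12 1.68-fold. Deletion and library series cannot be told apart, and with FPKM as deposited 1657 of 2842 genes were higher (58.3%, against 48.3%).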

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

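All tests of explanations in this part were chosen after the results had been seen.

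On the log2 scale, with 1 added to each value, 5 genes changed by 2-fold or more in opposite directions in a clr deletion and in mit1D or chp2D. They gave 7 differences in all. SPBC1289.14 is not among them, since its log2 fold changes were 3.38, 3.44 and 3.8 in the clr deletions but -0.9 in mit1D and -0.94 in chp2D. To be counted, the direct difference between the 2 deletions also had to pass adjusted p under 0.05. The genes were chosen for opposite changes against the same wild-type libraries, so passing this test adds no support. The amino acid permease gene per1 fell in clr1D (log2 fold change -1.95) and rose in mit1D (1.03), a difference of -2.98 ± 0.11 (SE). The glucose transporter gene ght5 rose in clr1D (1.16) and fell in mit1D (-1.31) and chp2D (-1.25), differences of 2.47 and 2.40, each ± 0.25. At the left end of chromosome II, SPBPB10D8.03 fell in clr3D (-1.53) and rose in mit1D, a difference of -2.67 ± 0.18, and SPNCRNA.1307 did likewise (-1.29 and 1.05), a difference of -2.34 ± 0.31. SPBC460.05, which the table places on a contig outside chromosomes I to III, fell in clr3D (-1.29) and rose in mit1D (1.58) and chp2D (1.43), differences of -2.87 and -2.73, each ± 0.25. Each of the 7 sets a group of the first library series against a group of the second, so the deletion and the library series cannot be told apart in them.

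The first pattern weighed was a set of 20 genes, 9 higher and 11 lower, changed 2-fold or more on the log2 scale, with 1 added to each value, alike in mit1D and chp2D and not by 2-fold on that scale in the same direction in any clr deletion, such as SPNCRNA.934, omt3, mei2 and gpd3. The set rests on this cutoff and its changes are not all absent from the clr deletions. For omt3, mei2 and gpd3 the log2 fold changes were -0.91, -0.69 and -0.89 in clr1D and -0.77, -0.45 and -0.71 in clr2D. In clr3D they were 0.85, 0.5 and 0. SPAC212.08c is in the set although its ratio of means rose in the clr deletions too (0.134 in wild type, 0.705, 0.552 and 0.922 in clr1D, clr2D and clr3D), and ght5 and SPBC460.05 are in the set and moved the opposite way in a clr deletion. When trends with GC content and gene length were removed from each library, 20 of the 20 remained past the threshold in both deletions, with a median absolute log2 fold change of 1.44 before and after; 19 of them had a GC value and could be corrected, and for those 19 this argues against the trends as the cause. With every library thinned to the lowest depth, 20 also remained, with a median of 1.43. The calls thus did not need the greater depth of the first series. Thinning leaves the expected level of each gene unchanged, so genes chosen for 2-fold changes were likely to remain. It therefore cannot weigh other differences that came with the shallower libraries. With 0 libraries labelled as wild type in the series of mit1D and chp2D, and 3 unlabelled columns with names of that series left unused, a difference between the library series cannot be told apart from a shared effect of both deletions, and both remain candidate explanations.

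The second pattern was the near absence of SPCC663.07c, SPNCRNA.1213 and SPCC663.08c from mit1D. Over the 3 genes and 3 mit1D libraries the highest value was 1.89% of the wild-type mean, while the flanking genes trm44 and osr1 stood at 84% and 88.5%, so the loss of these genes from the mit1D strain is a candidate explanation. In chp2D the lowest value was 62.6%, which argues against a function that Mit1 and Chp2 share as the cause. An effect of Mit1 alone was not separated from a strain variant, since all 3 mit1D libraries carry the same label. Among 44 other genes with a 2-fold fall on the log2 scale in any deletion, mit1 and SPNCRNA.1401 within it left out, the lowest level in mit1D was 15.2% of wild type, that of omt3; the weakly expressed Tf2-13 (0.0481 against 0.962) and SPBC12C2.14c (0.0216 against 0.403), singled out after their values were seen, fell by less on that scale but stood at lower shares of wild type.

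The third pattern was the clr2 signal in clr2D, at 76.2% of the wild-type mean. A mislabelled library is argued against by his7, the marker of that strain, whose lowest clr2D level was 2.15 times the highest level of the other 15 libraries. A part of the gene left in place may give such reads, but this cannot be told apart from other sources at 76.2%, because positions of reads within the gene are not in the table.

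With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 10 comparisons 1 of the 10 splits, the real one, gave as many changed genes. Every other split mixes both genotypes in each part, so differences between the groups enter the spread. Low counts in those splits therefore do not measure false calls. Within the first series replicate numbers pair the libraries, and some splits place both libraries of a pair in the same part. The real counts were 1178, 823, 1941, 1820 and 1513 for clr1D, clr2D, clr3D, mit1D and chp2D against wild type, with 1, 1, 0, 1 and 1 as the highest count among the other splits. They were 32 for clr1D with clr2D, 2353 for clr1D with clr3D, 2121 for clr2D with clr3D, 11 for mit1D with chp2D and 3044 for clr3D with mit1D, with 0, 1, 0, 0 and 1.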

How the results depend on the processing

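The test with voom on recovered reads was chosen after the results had been seen. Numbers of changed genes stayed within 1.5 times their value with FPKM as deposited, quantile normalization, either pseudocount, no filter and each library left out. With 1 library left out they ran from 876 to 1006 in clr1D, 559 to 699 in clr2D, 1576 to 1715 in clr3D, 1295 to 1683 in mit1D and 1061 to 1397 in chp2D. A similar number did not mean the same genes. Against wild type, FPKM as deposited kept 73.9% (clr1D) to 84.9% (mit1D) of the main calls in the same direction. Leaving out 1 library kept 63.4% (clr2D without clr2D replicate 2) to 83.2% (mit1D without wild-type replicate 1). Fits of only the 2 groups kept 38.9% (clr2D) to 82.2% (chp2D), and either pseudocount at least 98.7%. A replicate block raised clr1D to 1977 and clr2D to 1534 and moved no other count by more than 1.5 times. Fits of only the 2 groups have fewer libraries to estimate the spread and gave 543 in clr1D, 323 in clr2D and 1082 in clr3D. They gave 1493 for clr1D with clr3D and 1253 for clr2D with clr3D. Subtelomeric rises fell to 19 in clr1D and 17 in clr2D. With equally few libraries, such fits gave 1547 in mit1D, 1406 in chp2D and 15 for mit1D with chp2D. The number of libraries alone therefore does not account for the larger losses. The main fit uses 1 spread for both library series, although replicates differed more in the first. A chi-square between the recovered reads of 2 replicates, divided by its degrees of freedom, measured this. It was 11.4 to 44.95 within wild type and the clr deletions and 1.73 to 5.88 within mit1D and chp2D. This ratio also grows with depth, which was lower in the second series. The shared spread may thus be too small for the first series, but the cause of the losses was not tested. A pseudocount of 5, which by construction shrinks folds of weakly expressed genes, lowered the 2-fold counts from 52 to 21 in clr1D, 41 to 16 in clr2D, 47 to 14 in clr3D, 53 to 26 in mit1D, 34 to 17 in chp2D, 11 to 7 for clr1D with clr2D, 26 to 12 for clr1D with clr3D, 14 to 7 for clr2D with clr3D and 82 to 40 for clr3D with mit1D. A pseudocount of 0.1 raised them to 63 in chp2D, 50 for clr1D with clr3D and 34 for clr2D with clr3D. The voom test, which adds no such constant to FPKM, gave 82 in clr1D, 65 in clr2D, 71 in clr3D, 62 in chp2D, 51 for clr1D with clr3D and 39 for clr2D with clr3D; it also changed 7 genes instead of 11 between mit1D and chp2D, and the cause was not tested. Within 50 kb of the ends, where 33 genes were tested in place of 117, rises numbered 19, 19, 21, 17 and 14 in clr1D, clr2D, clr3D, mit1D and chp2D. An estimated correlation, which widens the list tests, left 2 of 50 list calls. Of the 50, 42 were kept with FPKM as deposited, 41 with quantile normalization, 49 with either pseudocount, 43 without the filter and 49 with a replicate block. The 675 results for named genes had 9416 alternative values, of which 8771 stayed on the same side of the threshold, 602 were no longer past it, 43 became so and 0 changed direction; the cause was not tested. At these depths and the 1 dispersion simulated, the self-test found 66% of changes of 1.2-fold, so smaller changes are incompletely listed.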

Other observations

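The test of neighbouring genes in this part was chosen after the results had been seen. Among 3777 pairs of adjacent genes that do not overlap, pairs with both genes changed by at least 1.2-fold in the same direction numbered 62 in clr1D, 53 in clr2D, 66 in clr3D, 65 in mit1D and 45 in chp2D. When gene order was permuted 1000 times, the means were 10.1, 6.5, 14.3, 19.5 and 12.1 and the highest values 19, 16, 29, 33 and 24, a permutation p of 0.001 in each, the smallest that 1000 permutations can give. Pairs in opposite directions numbered 17, 11, 12, 16 and 15, against permuted means of 9, 5.7, 13.7, 16.5 and 11.5.

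Some regions in which neighbours moved together were singled out after their values were seen. Left of centromere 1, per1 stood at 24.5 in wild type, 5.62 in clr1D, 13.1 in clr2D, 31.1 in clr3D, 50.9 in mit1D and 45.8 in chp2D. On the other side of that centromere, emc5 stood at 64.7 in wild type and 36.9, 41.3, 62.8, 56.7 and 63.3 in the 5 deletions in the same order. Near SPNCRNA.1672 on chromosome II, the centromere protein gene cnp3 stood at 22.8 in wild type, 14.4, 14.5 and 14.1 in clr1D, clr2D and clr3D, and 22.2 and 24.1 in mit1D and chp2D, and abp2 at 11.1, 5.57, 5.42, 5.83, 13.1 and 13.3. Near the right end of chromosome I, pdc102 stood at 1.09 in wild type, 4.19, 4.99 and 5.68 in the clr deletions, and 1.08 and 1.11 in mit1D and chp2D. The amine oxidase gene cao1 stood at 75.8 in wild type, 70.0 in clr2D and 79.2 in clr3D, and at 32.0, 36.2 and 34.1 in clr1D, mit1D and chp2D.

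The retrotransposon Tf2-13 stood at 0.962 in wild type and at 0.0327, 0.0481 and 0.0162 in clr3D, mit1D and chp2D, and was higher in clr1D and clr2D than in clr3D by 0.95 and 0.97 on the log2 scale. How reads shared by Tf2 copies were assigned is not known, and whether each strain carries this copy was not tested. SPBC1289.14, which rose in the clr deletions, fell in mit1D and chp2D, to 0.465 and 0.425 from 1.73. Of genes next to a deleted gene, usp103 stood at 40.6 in mit1D against 23.9 in wild type, and mhf1 at 41.2 in clr1D against 33.6. In a principal component analysis of the 18 libraries the first 4 components held 46.4, 13.5, 11.5 and 6.8% of the variance.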
